A study of Drosophila melanogaster with 2 samples.

How the data were processed

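Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed in Drosophila melanogaster Kc cells, an established cell line of embryonic origin, with an antibody named for Trl. Trl encodes the GAGA factor, a DNA-binding protein that recognises GA-rich sequence. The labels list 2 samples, 1 of ChIP and 1 of input chromatin. A peak list was analysed for the ChIP sample. The series design text speaks of 2 replicates for ChIP-seq. Per the labels' protocols, material was crosslinked in 1.8% formaldehyde for 15 minutes, sonicated for 15 minutes, incubated overnight with antibody and recovered on protein A beads, and an aliquot without antibody gave the input. The growth protocol in the labels describes fly collection rather than cell culture, so culture conditions are not given in the sources used here.

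Reads were aligned with Bowtie to the BDGP5 assembly, per the submitters' processing notes. Peaks were called with MACS, per the file headers. The versions, the peak-calling settings, the treatment of duplicate reads and whether libraries were pooled are not given in the sources used here. The series design text names chromatin input as the control. Each peak in the deposited file has a chromosome, a start, an end and a score. The score deposited by the authors was used as it stands, and its scale is not stated in the file. The highest score was 3233.06, which equals -10 log10 of the smallest double-precision number. This value, shared by 3 peaks, prompted a test of the other 4 scores above 3206.7. All 4 equalled -10 log10 of a whole multiple of that number within 0.006, where 0.43 matches would be met by chance, from the share of matching 2-decimal values within 1 unit of each score (exact p = 2.08e-05 for all matching). Scores were therefore read as -10 log10 of the p-value of the peak caller. Read depth is unknown, since the list holds no counts, and peak numbers depend on it. Coordinates below are 1-based positions in BDGP5.

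Peaks were analysed with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and plotted with Matplotlib 3.10.9. Each group had 1 sample, so no difference between samples was tested. All p-values below treat the peaks, or windows of the genome, of this one list as units. They describe this list and carry no error between cultures or libraries. The length of each chromosome arm was taken as the end of its last peak. Peak numbers per arm were compared with the numbers expected from these lengths by 2-sided exact binomial tests with Benjamini-Hochberg adjustment, over all 11 chromosomes and scaffolds and over the 5 major arms. Since the binomial test treats peaks as independent and peaks were clustered, arms were also compared by permuting 500 kb windows (100000 permutations, 2-sided), with 95% bootstrap intervals over windows. Neighbouring windows were treated as independent. Gaps between neighbouring peaks were compared with 1000 random placements of the same peaks, without overlap, on the same chromosome. The smallest p these placements can give is 0.002, and the smallest that the permutations can give is 1e-05. Medians and correlations across peaks were compared by 2-sided permutation tests with 100000 permutations, and peaks are not independent replicates.

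The binomial test over arms, the spacing test and most of their alternatives were fixed before the data were examined. The window permutation, the within-window placement with and without merging, the test of chromosome 4 without the scaffolds, the comparisons of medians, of score quartiles, of neighbouring scores and of arm ends, and the counting of runs were added afterwards. The peaks named are the 15 with the highest score, with ties broken by width and then position, a rule fixed before the data were examined. The widest peaks with the tied score, the largest runs, the densest windows and the longest peak-free stretches were chosen after their values were seen. The tests were tested on 50 simulated lists per setting with about the number, widths and arm lengths of the real peaks. With no effect planted, the binomial and window tests called X in 0% of lists and the spacing test was significant in 2%. With the density of X raised 1.25-fold, both arm tests called X in 100% of lists. With 0.3 of the peaks planted beside another peak, the spacing test was significant in 100%, and the binomial and window tests called X in 0% of lists. In these lists the number of peaks per arm was drawn before peaks were planted beside others, so they do not measure what clustering does to the binomial p-values. In the lists with no effect or with X raised, positions were drawn evenly along each arm, without the clustering of the real list. Their shares of calls therefore do not give the error rate or power of the arm tests on the real list. A test of neighbouring scores over all consecutive peaks was significant in 8% of lists with no effect planted. It did not divide the pairs by gap and included pairs across arms. This share is therefore not the error rate of the tests of neighbouring scores reported below.

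The gene table at hand follows Release 6 of the genome, whereas the peaks are in BDGP5. Peaks were therefore not assigned to genes, exons, introns or transcription start sites, and their sequences were not searched. The comparisons of promoters, GAGA elements, other sequence motifs and gene lists that had been planned were not made.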

Results

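The binding profile of the GAGA factor, encoded by Trl, was measured by ChIP-seq in Kc cells. The GAGA factor binds GA-rich elements and is known to keep chromatin open at promoters. The data comprised 1 ChIP sample and 1 input sample, the control named by the series design. The list of the ChIP sample held 3842 peaks on 11 chromosomes and scaffolds of the BDGP5 assembly. These peaks covered 2.34 Mb. The number of reads behind them is unknown, so neither a weak peak nor the absence of one can be tied to a depth. The series design speaks of 2 replicates for ChIP-seq, and whether the list pools replicate libraries is not given. There was no replicate list, so every value below is that of a single list.

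Peaks of the GAGA factor were short and their scores spanned a wide range. The median width was 522 bp, with quartiles at 391 and 738 bp and extremes of 148 and 3086 bp. The median score was 379.8, with quartiles at 117.6 and 1295, and 811 peaks (21.1%) scored under 100. The lowest score was 50.11. Stronger peaks were wider. The median width was 353 bp in the lowest quartile of scores, 451.5 bp in the second, 591.5 bp in the third and 847 bp in the highest. Across the 3842 peaks, width and score were correlated with a Spearman rho of 0.73 and a Pearson r of 0.68 (permutation p = 1e-05 for each, the smallest possible). Among the 3547 peaks scored under 3100, rho was 0.69 and r was 0.60 (permutation p = 1e-05 for each). Width and score come from the same peak calls on the same reads. The test therefore cannot tell a trait of binding from a relation built in by the caller.

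At the upper end of the score, 267 peaks (6.95%) shared the value of exactly 3100, and 28 peaks scored above it. The tied peaks had a median width of 1068 bp, against 932.5 bp for the 28 peaks above them. This difference of 135.5 bp (95% bootstrap interval -81 to 253) did not pass a permutation test (p = 0.20). Against all 93 untied peaks that scored above 2800, whose median width was 920 bp, the tied peaks were wider by 148 bp (interval 57 to 253, permutation p = 0.0109).

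**Figure D1:**
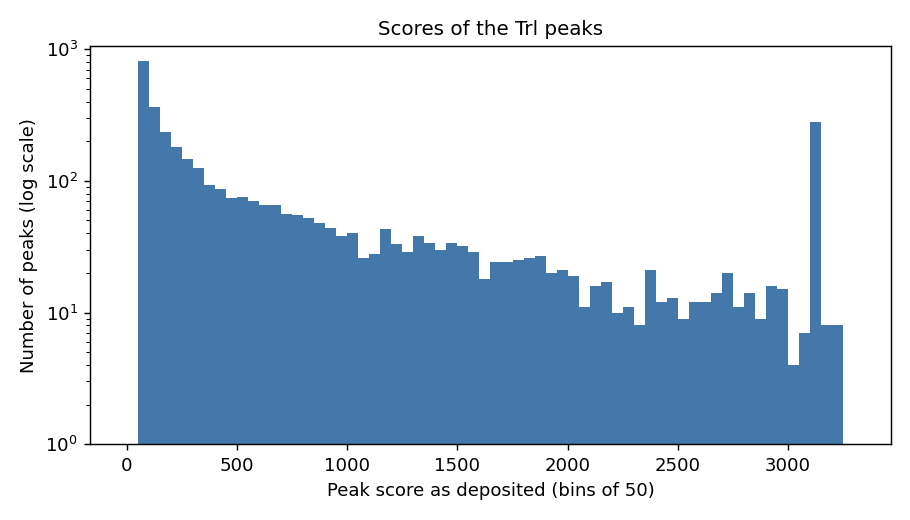
Histogram of the deposited scores of the 3842 peaks in bins of 50, with the number of peaks on a log axis. Counts fall from the lowest scores upwards, and a single bin at 3100 holds the 267 tied peaks.

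The 15 peaks with the highest score lay on 3R (5 peaks), 3L and X (4 each) and 2L (2), with none on 2R. Their scores ran from 3160 to 3233.06 and their widths from 714 to 1731 bp. The highest score, 3233.06, was shared by 3 peaks. These lay on 3L from 17562676 to 17563839, on 3R from 11301612 to 11302424 and on 3R from 5914826 to 5915608. They were followed by a peak on 3L from 19784452 to 19785321 with a score of 3222.27, and by one on 3R from 14991113 to 14991988 with a score of 3221.92. On X, the highest-scoring peak lay from 3642557 to 3643366 with a score of 3212.69, and on 2L it lay from 21827975 to 21829257 with a score of 3183.54. The tied peaks, which rank below these 15 by the score as deposited, included wider ones. The 15 widest tied peaks ran from 2105 to 2983 bp, and the widest lay on X from 7588882 to 7591864. The next widest lay on 2R from 14243007 to 14245608, with a width of 2602 bp, and on X from 15705436 to 15707940, with a width of 2505 bp.

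Along the genome, 3787 peaks (98.6%) lay on the arms 2L, 2R, 3L, 3R and X. X carried the most peaks per Mb and 2L the fewest. Over 500 kb windows, X held 38.3 peaks per Mb (95% bootstrap interval 33.3 to 43.6, 44 windows) and 2L held 27.9 (23.8 to 32.1, 45 windows). The other arms lay between them, with 33.3 per Mb on 2R (28 to 39), 32.2 on 3L (27.7 to 37.3) and 30.8 on 3R (27 to 34.8). Windows within an arm differed widely, with an SD of 17.8 peaks per Mb on X and 14.5 on 2L. The density of X was 1.24 times that of the 4 autosomal arms combined (interval 1.051 to 1.44, window permutation p = 0.00827). Against single arms, X was 1.37-fold above 2L (interval 1.13 to 1.69, adjusted permutation p = 0.0118) and 1.24-fold above 3R (1.03 to 1.498, adjusted permutation p = 0.0494). The ratio of X to 3L was 1.19 (0.97 to 1.45, adjusted permutation p = 0.13) and that of X to 2R was 1.15 (0.93 to 1.42, adjusted permutation p = 0.20), and neither passed the threshold. Each arm was counted up to its last peak. Any stretch without peaks beyond it would lower the density of that arm, and could change these ratios and the order of the arms.

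**Figure D2:**
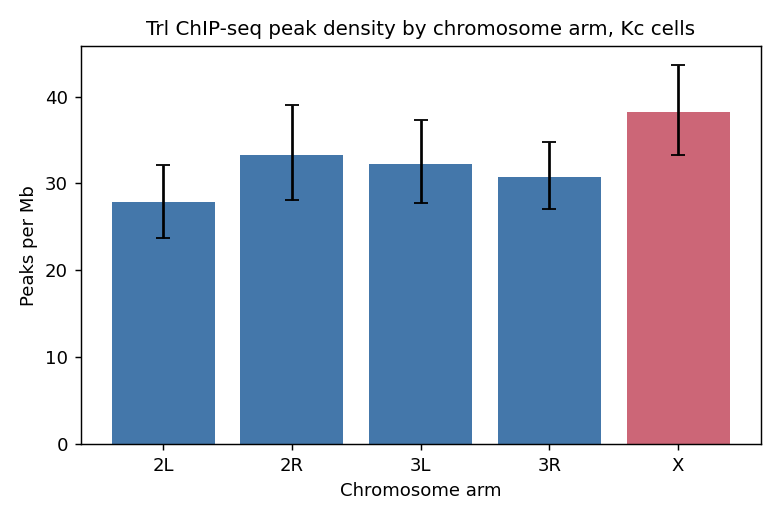
Mean number of Trl peaks per Mb (vertical axis) on each major chromosome arm, over 500 kb windows, with 95% bootstrap intervals over windows as error bars. X has the highest mean, 38.3 per Mb, and 2L the lowest, 27.9 per Mb.

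In the binomial test over the 5 major arms, X held 1.17 times the number expected from its length (846 peaks, adjusted p = 1.94e-06) and 2L held 0.855 times (631 peaks, adjusted p = 2.11e-05). The arms 2R, 3L and 3R did not depart from expectation, with ratios of 1.03, 0.997 and 0.957. When the scaffolds were included, as had been planned, the total length grew by the sparsely covered scaffolds. In this exact test every major arm stood above expectation, from 1.13-fold on 2L (adjusted p = 0.000978) to 1.55-fold on X (adjusted p = 1.09e-38), so the direction for 2L, 3L and 3R depends on the scaffolds. Among the 50% of peaks with the highest score, counted on the major arms alone, both departures remained significant in the exact binomial test, with ratios of 1.12 for X (adjusted p = 0.0328) and 0.791 for 2L (adjusted p = 2.39e-05). Among the highest 25%, the exact binomial ratio was 1.08 for X (adjusted p = 0.50) and 0.842 for 2L (adjusted p = 0.08). Neither passed the threshold in this smaller set, although the ratio of 2L was near the 0.855 of all peaks.

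By single quartiles of the score in the window test, the ratio of X to the autosomal arms was 1.30 in the lowest quartile and 1.34 in the second (adjusted permutation p = 0.015 for each). It was 1.20 in the third (adjusted permutation p = 0.118) and 1.11 in the highest (interval 0.80 to 1.48, adjusted permutation p = 0.44). The ratio of the highest quartile minus that of the lowest was -0.19, with an interval from -0.55 to 0.20, so the quartiles were not shown to differ. The median score was 351 on X and 401 on the autosomal arms. That difference of -50.4 (interval -117 to 17.7) did not pass a permutation test (adjusted p = 0.22). Peaks on 2L had a median score of 306, below the 425 of the other autosomal arms (adjusted permutation p = 0.0247).

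Chromosome 4, a small chromosome rich in heterochromatin, carried 26 peaks, or 20.4 per Mb (exact Poisson interval 13.3 to 29.9, counting error only). Its number was 0.839 times the expectation over all chromosomes and scaffolds, which was not significant (exact binomial test, adjusted p = 0.417). The ratio was 0.581 among the 50% of peaks with the highest score and 0.387 among the highest 25%, neither significant (exact binomial tests, adjusted p = 0.135 and 0.109). This expectation includes the length of the sparsely covered scaffolds. Over the major arms and chromosome 4 without the scaffolds, a comparison chosen after seeing the data, chromosome 4 held 0.636 times the expected number (exact binomial test, adjusted p = 0.0359). In that comparison the ratio was 0.438 among the highest 50% of scores (9 peaks, exact adjusted p = 0.0185) and 0.291 among the highest 25% (3 peaks, exact adjusted p = 0.0657). With runs of peaks at gaps under 2 kb counted once it was 0.591 (16 runs, exact adjusted p = 0.0654). This ratio was no nearer to 1 than the 0.636 for peaks, and the test had fewer units, 16 runs in place of 26 peaks. Beyond this, why the call on chromosome 4 was lost was not tested. Its peaks were narrower than those of the major arms, with medians of 352.5 and 524 bp (adjusted permutation p = 0.0247). The median score was 157 on chromosome 4 and 386 on the major arms, which did not pass the test (adjusted permutation p = 0.22). Its strongest peak lay from 521964 to 522736 and had the tied score of 3100. The heterochromatin scaffolds 2RHet, 3LHet and 3RHet held 20 peaks in all, with a median width of 260.5 bp and a median score of 120. The unplaced scaffolds U and Uextra held 9 peaks.

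Peaks of the GAGA factor were clustered. Of the 3831 gaps between neighbouring peaks, 1288 (33.6%) were shorter than 2 kb, against 6.38% ± 0.383 (SD over 1000 random placements). This was a 5.27-fold excess, larger than in any placement (permutation p = 0.002, the smallest possible). The excess was greatest at the shortest distances, with 511 gaps under 250 bp against a random mean of 32.4. The smallest gap was 1 bp. Short gaps can also arise where the caller splits 1 enriched region, and these values do not settle which applies. The excess faded at 2 to 5 kb, with 365 gaps against 339. At the other extreme, 323 gaps lay between 100 kb and 1 Mb, against 158 at random. After peaks closer than 500 bp were merged, which left 3089 peaks, the excess of gaps under 2 kb was 3.36-fold (placement permutation p = 0.002). When peaks were placed only within their own 100 kb window, it was 3.22-fold (placement permutation p = 0.002). With both changes together it was 2.27-fold, with 17.4% of gaps under 2 kb against 7.65% (placement permutation p = 0.002).

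**Figure D3:**
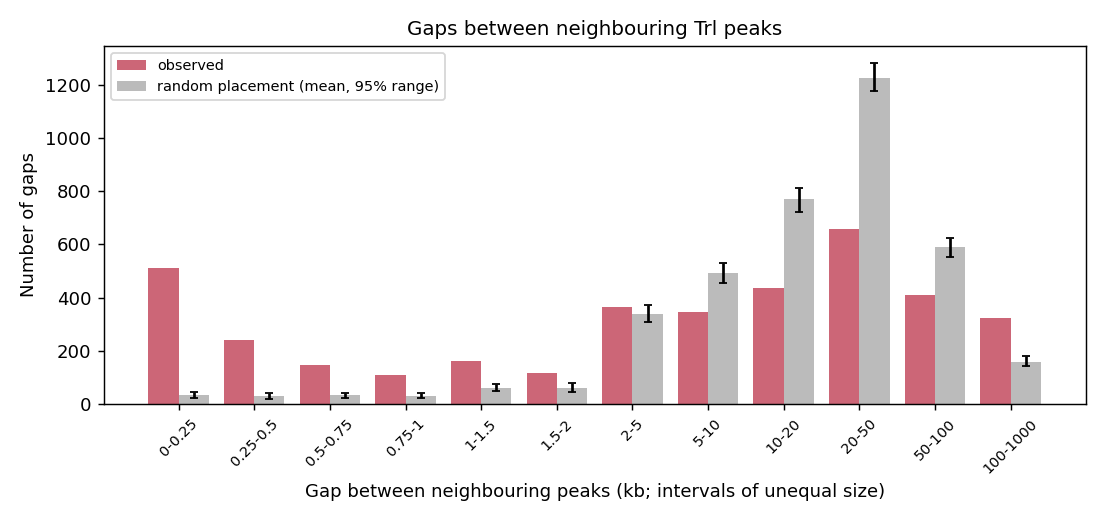
Number of gaps between neighbouring peaks (vertical axis) by gap length in kb (horizontal axis, intervals of unequal size), as observed and under 200 random placements (mean, with the central 95% as error bars). Observed gaps exceed random ones below 2 kb and above 100 kb and fall below them from 5 to 100 kb.

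Joined at gaps under 2 kb, the list formed 2554 runs, of which 1741 were single peaks and 813 held 2 or more. Runs of 2 or more contained 2101 peaks (54.7%). Peaks in runs scored higher than single peaks, with medians of 493 and 280.5 (permutation p = 1e-05), and were wider, with medians of 546 and 492 bp (permutation p = 1e-05). The tied score of 3100 was held by 171 of the peaks in runs (8.14%) and by 96 single peaks (5.51%), a difference that passed Fisher's exact test (2-sided p = 0.00142). The largest run comprised 12 peaks on X from 3578930 to 3591253, of which peaks covered 6.998 kb. A run of 8 peaks lay beside it on X from 3565733 to 3575102, and another of 8 peaks lay from 3666764 to 3675329. On 2R, 11 peaks lay from 6417881 to 6433629. A run of 10 peaks on X from 7595312 to 7604445 had a median score of 1525. The most completely covered of the 7 runs with 8 or more peaks lay on X from 2186477 to 2200950, where 8 peaks covered 87.5% of 14.5 kb and had a median score of 2320.

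**Figure D4:**
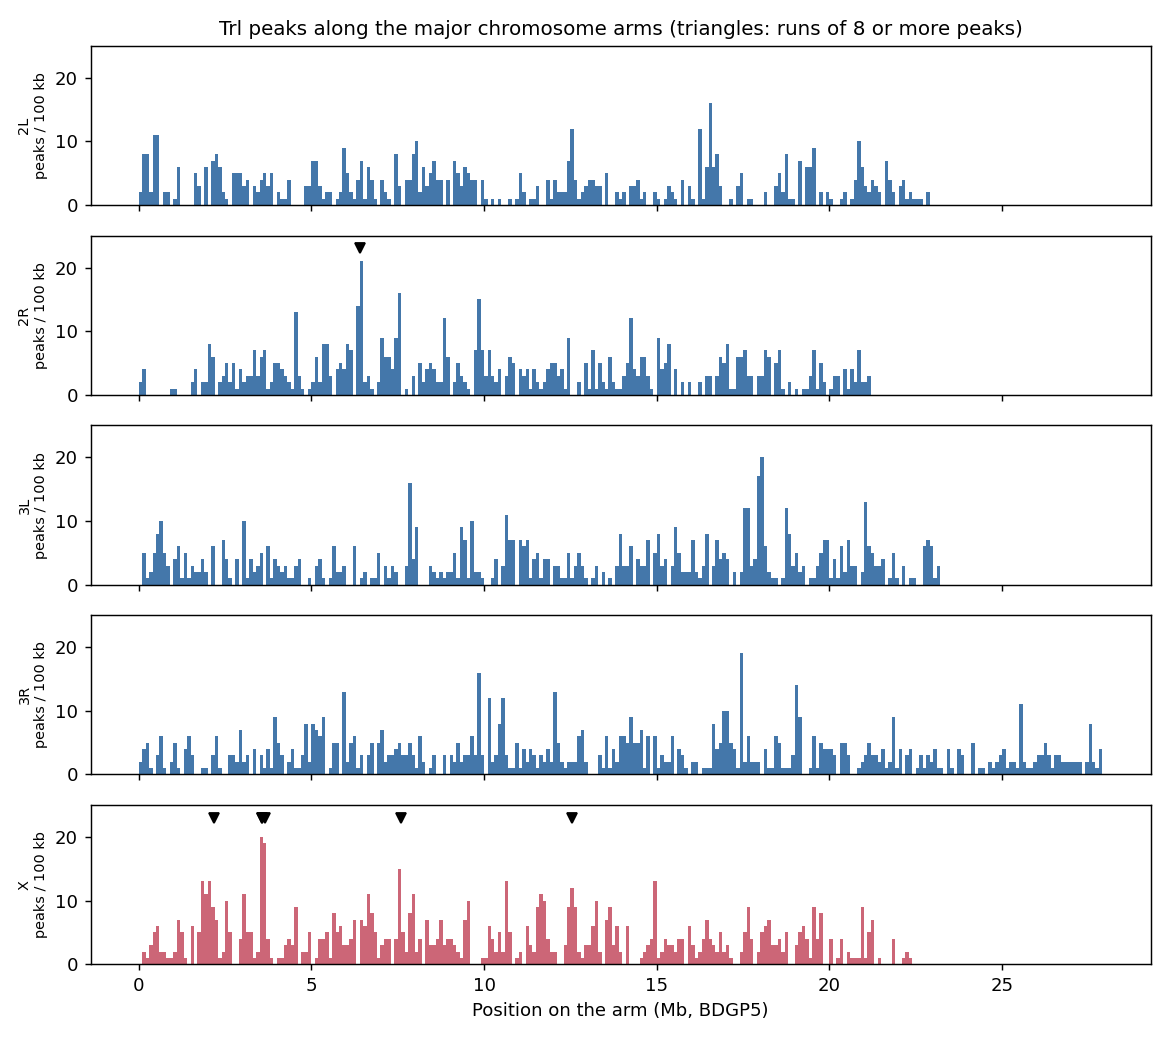
Number of Trl peaks in each 100 kb window (vertical axes) along the 5 major arms (horizontal axis, position in Mb in BDGP5), with triangles at runs of 8 or more peaks. The fullest window holds 21 peaks, on 2R, and 6 of the 7 marked runs lie on X.

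The densest 100 kb windows lay on several arms. The window on 2R from 6400001 to 6500000 held 21 peaks. The windows on 3L from 18000001 to 18100000 and on X from 3500001 to 3600000 held 20 each. Those on 3R from 17400001 to 17500000 and on X from 3600001 to 3700000 held 19 each. In 1000 random placements of single peaks, the fullest window of the major arms had a median of 10 peaks and never more than 15. These placements do not keep runs together, so they cannot tell dense windows apart from the clustering at short gaps. The longest stretch without a peak on the major arms, up to the last peak of each, was 817 kb on 2R, from 160230 to 976892. It was followed by 538 kb on the same arm from 1014316 to 1551831 and by 508 kb on 2L from 4372190 to 4880504. Both stretches on 2R lie in its centromere-proximal 2 Mb. Any stretch beyond the last peak of an arm was left out, since arm lengths ended there. When whole runs were placed at random, the longest stretch had a median of 381 kb and a maximum of 711 kb over 1000 placements.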

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

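Of the 53 recomputed values with a test, 34 kept their direction and their side of the threshold, 9 kept the direction but were no longer significant, 1 kept the direction and became significant, and 9 changed direction. The changes of direction concerned 2L, 3L and 3R, and the losses 2L, 2R and 3L. The tally includes the highest 50% and 25% of scores with the scaffolds, whose length raises the ratios of the major arms. It leaves out these score settings on the major arms alone. Chromosome 4 without the scaffolds, by runs or by score, is also left out. The tally therefore does not measure how robust the calls are. The number of peaks, which has no test, was 3842 as deposited, 3089 after merging and 3031 at scores of 100 or more, the last 2 chosen after seeing the data. Restricting the binomial test to the major arms moved the ratio of observed to expected peaks to 0.855 on 2L, 0.997 on 3L and 0.957 on 3R, below 1 in place of above it, and to 1.03 on 2R, no longer significant. The cause is the construction of the test, since the scaffolds add length with few peaks. Among settings chosen after seeing the data, counting runs once on the major arms gave 0.852 on 2L, 1.07 on 2R, 1.01 on 3L and 0.954 on 3R, and keeping peaks scored 100 or more gave 0.791, 1.06, 1.02 and 0.970 for the same arms. Adding chromosome 4 to the major arms, also chosen after seeing the data, gave 0.858, 1.04, 1.0006 and 0.961 for these arms, and 0.636 for chromosome 4 (adjusted p = 0.0359, exact test) in place of 0.839. The scaffolds' length is again the difference. Counting runs once in that setting gave 0.591 for chromosome 4, not significant. With the scaffolds included, the 50% of peaks with the highest score gave 1.06 on 2L and the highest 25% gave 1.13, neither significant. In the highest 25% the ratio was close to the 1.13 of all peaks, on fewer peaks. Why the ratio fell in the highest 50% was not tested. X kept a ratio above 1 past the threshold in all 6 of these binomial alternatives, and in the highest 50% on the major arms alone (1.12), though not in the highest 25% there (1.08). The excess of short gaps was past its threshold in all 8 alternatives. It ran from 2.27-fold with merging and within-window placement together, chosen after seeing the data, to 10.9-fold for the highest 25% of scores. In that set 17.8% of gaps were under 2 kb against 1.63% at random, and over all peaks 33.6% against 6.38%. The folds of lists of unlike size therefore do not rank the strength of clustering. Alternatives for promoters, GAGA elements, their relation to the score, other motifs and gene lists were not run, as they need a BDGP5 sequence or annotation, which was not used here. No paired analysis was possible because each group had 1 sample, and for the same reason no sample could be left out. Unknown read depth limits what the weak peaks can show.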

Other observations

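All tests in this part except the placement after merging alone were chosen after the peak list had been seen. For the placement after merging alone, the within-window placement without merging and for the interior windows, runs and highest score quartile of X, what each explanation predicts was written down before the result; the other tests followed the value they measure.

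Long runs of peaks were more frequent on X. Of the runs on X, 15 (2.79%) held 5 or more peaks, against 25 (1.27%) on the autosomal arms (Fisher's exact test, 2-sided p = 0.0184). Since runs were joined at gaps under 2 kb, a higher peak density alone would also lengthen them. The test does not allow for this. Of the 7 runs with 8 or more peaks, 6 were on X, and 3 of these lay between positions 3565733 and 3675329. The centromere-proximal 2 Mb of the major arms held 22.8 peaks per Mb, against 33.3 in the remaining windows (permutation within arms, adjusted p = 0.014). On 2L, 3L and X this end was counted back from near the last peak. Any stretch without peaks beyond it was left out, so the proximal density of these arms may be overstated. By this count the proximal density was lower in 3 of the 5 arms. It was 9 against 35.8 on 2R, 20.5 against 40.1 on X and 22.5 against 31.4 on 3R, while 2L had 29.5 against 27.7 and 3L had 32.5 against 32.2. Without the proximal windows of 2R, the values were 26.3 and 33.3 (permutation p = 0.0901), so with the ends counted this way the call rests on 2R. The distal 2 Mb held 30.9 peaks per Mb against 32.5 (adjusted permutation p = 0.677).

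The first pattern is the tie at 3100, which may be a fixed score written in place of a p-value that was too small for double precision and became 0. The 4 scores between 3206.7 and the maximum fell on multiples of the smallest representable number, as p-value underflow requires, where 0.43 would by chance (exact p = 2.08e-05). The 3 peaks at the maximum prompted this test and were left out of it. The alternative that 3100 is an ordinary value of the score is at odds with the width of the tied peaks, which exceeded that of untied peaks scored above 2800 by 148 bp (permutation p = 0.0109), and with the 31 untied peaks within 100 units of it. Whether the tied peaks are weaker than the 28 scored above them stays open, as the width difference of 135.5 bp lay within its error. If the tie stands for underflow, the peaks at 3100 would be the strongest of the list and the 15 named by score would not be.

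For the second pattern, the clustering of peaks, broad regional differences in density over 100 kb or more are argued against as the whole cause. The excess was still 3.22-fold with placement inside 100 kb windows, against 5.27-fold without. This placement keeps the count of each window, which short runs also raise, so the fall cannot be assigned to regional differences. With merging as well the excess was 2.27-fold. Splitting of one enriched region by the peak caller stays open for all gaps under 2 kb. The excess after merging was 3.36-fold, but the bound set for it beforehand was wrong. Merging at 500 bp leaves longer gaps as they were, and all 535 gaps under 2 kb after it were the gaps of 500 bp to 2 kb present before it, so the test could not remove splits of that length. Gaps under 250 bp were 2.11 times as frequent as gaps of 250 to 500 bp, against 1.054 at random, which splitting and closely spaced binding sites would both give. Uneven mappability or composition within 100 kb and clustered binding sites remain as untested explanations for the rest.

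The third pattern is the higher density on X. Without the first and last 1 Mb of each arm the ratio of X to the autosomal arms was 1.27 (window permutation p = 0.00288). The excess was therefore not confined to the ends of the arms. The last 1 Mb was counted back from the last peak, so any stretch without peaks beyond it is missing from both ratios. Understated arm lengths therefore stay open as a cause of the difference over whole arms. Dense clusters with gaps under 2 kb are argued against as the whole cause. Runs counted once gave 1.17 (window permutation p = 0.0241), though this is nearer to 1 than the 1.24 for peaks. Dense stretches with longer gaps still count as many runs. An example is X from 3500001 to 3700000, where adjoining 100 kb windows held 20 and 19 peaks. Whether such stretches carry the excess was not tested. More reads from X in the library cannot be told apart from other causes, because the ratio of 1.11 in the highest score quartile has an interval from 0.80 to 1.48 and the list holds no read counts. The design names no group that would give a biological explanation, and none was tested.

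Scores of peaks within 2 kb of each other were weakly related, with a Spearman rho of 0.091 and a Pearson r of 0.12 over 1288 pairs (adjusted permutation p = 0.00203 for rho). The Spearman correlation was 0.129 for the 753 pairs with gaps under 500 bp (adjusted permutation p = 0.002) and 0.043 for the 535 pairs with gaps of 500 bp to 2 kb (adjusted permutation p = 0.321). For pairs 2 kb or more apart rho was 0.062 (adjusted permutation p = 0.00203), and whether any of these values differ from each other was not tested. Over the close pairs, the weaker member had a median score of 182 and the stronger one of 1234, against 135 and 889 for pairs 2 kb or more apart.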
